A study of Mus musculus with 10 samples.

How the data were processed

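Gene expression was measured in mouse small bowel on nylon-membrane cDNA arrays with 6144 features and 1 colour: per the labels' protocols, cDNA carried biotin and was detected by a colour reaction with beta-galactosidase joined to streptavidin. There were 10 arrays in 5 groups of 2: sham, and days 1, 3, 7 and 14 after abrasion of the bowel. Groups and replicate numbers came from the sample titles. Per the labels, 6 mice were used per day, 3 sites of 1 cm were abraded, and the sham RNA pooled laparotomy-only bowel from 4 times. The design text says that duplicates came from different cohorts of mice. The sham arrays thus held pooled RNA. Whether an array of a day held RNA of single or pooled mice is not given in the sources used here. The p-values therefore measured the spread between these samples, which may be partly technical. The labels name C57BL/6 as the strain in one field and BALB/c in another, and the text on labelling speaks of livers; the tissue field and the titles name small bowel, which was followed. The treatment text of the day 7 and day 14 samples says day 3; their titles were followed, so the meaning of these days rests on the titles.

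The values deposited by the authors are a ratio without unit, with no scale given in the sources used here. The 2 sham values of a feature added up to 2 in all but 1 feature (tolerance 0.0005), so each value is relative to the mean of the sham arrays of its own feature. The median ratio was 1 on each of the 10 arrays, and 1005 features were at exactly 1 on both sham arrays. A lowest value shared by 2 or more arrays (tolerance 0.0015) was read as a floor set by the authors before the division. It was found in 1407 of the features tested, against 61 with a shared highest value. Between 20.8% and 21.5% of features were at the floor on an array. The 580 features at the floor on all 10 arrays were left out, and 5564 were tested. Brightness and background are not given by a ratio, so a difference is a relative one, and a group at the floor on both arrays gives only a bound.

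Genes were named from the platform annotation: 2194 features had 1 gene (1909 distinct genes), 89 had several and were not named, and 3861 had none. Entrez identifiers matched to the GRCm38.p6 gene table changed 0 symbols. Of 20 genes fixed in advance as of interest for adhesions, 0 had a feature named here.

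The test was planned for brightness values on log2. Ratios were put on log2 instead, which leaves differences between groups unaffected by the division. As the medians of the arrays lay within 0.1, the authors' normalization was kept. Group means were fitted over all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual degrees of freedom). Each day was set against sham and against the day before it, and limma's F test took the 4 contrasts against sham together. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over 5564 features. Errors after ± are standard errors of the fit, with n = 2 arrays per group. For members of gene lists not named by the rule they come from the same fit over the 1718 genes of the list tests.

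Of 44 gene lists fixed in advance, the 9 with at least 5 measured members were tested with limma's camera (preset correlation 0.01), with an estimated correlation and fry beside it. A gene with several features was represented by that with the highest mean. This rule was made for brightness; on a ratio it favours features with higher day values, and the mean of all features was the alternative. Named genes were chosen by a rule set before the data were examined: per day, the 10 with the largest rise and the 10 with the largest fall among those past the threshold, filled up by the smallest p among features whose day arrays both lay above, or both below, both sham arrays; for successive days 5 each way; for the F test the 10 smallest p. Beside a list, 2 to 4 members were named.

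Arrays with the same replicate number deviated together. The difference between replicates 1 and 2 correlated across features between groups with r from 0.39 to 0.71 in all 10 pairs of groups. By the rule set in advance the numbers therefore pair the samples, with the cohorts of the design text as a possible origin, and a fit with the replicate number as a block (4 residual degrees of freedom) was the alternative. Errors and p-values of the Results come from the fit without block unless stated, so they leave this pairing out. Features are not independent replicates.

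Feature numbers follow a grid with 32 columns, read from the period of the autocorrelation. A correction for position was added after the data were examined: per array and per block of 1024 features, a local surface (loess, span 0.3) was subtracted. It took between 10.0% and 32.9% of an array's log2 variance. It was also combined with the replicate block. Further alternatives were quantile normalization, median centring, a pseudocount of 0.738, a variance trend, array weights, the groups compared alone, a threshold of 0.1, each array left out in turn, and, added later, leaving out features at the floor on 5 or more arrays.

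The fits were tested on simulated data for day 14 against sham over 5564 features, with the spread and replicate effects of the blocked fit. Of 100 features changed by 1 on the log2 scale the fit without block recovered 17%, and of 100 changed by 2 it recovered 84%, with 0 unchanged features called. With the replicate block these shares were 79% and 100%, with 7 unchanged features called. With the measured position surfaces added to the simulation, they were 6% and 76% without block, and 79% and 100% with position correction and block, with 8 unchanged features called. The spread and replicate effects already held the position trend, so it entered more than once there. Recovery without block may therefore be understated in that setting. The surface added was the one that the correction itself estimates, and the spread and replicate effects came from the blocked fit. The simulation thus favoured the fit with position correction and block. It does not show that this fit suits the measured data. Camera recovered 9 of 9 lists shifted by 0.5 among 1718 genes. In that simulation the noise was independent between genes, no position surface was added and all members shifted equally. It therefore does not give the power of camera on the measured lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.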

Results

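Scraping of the bowel wall is a model of intra-abdominal adhesion, the scar-like bridging of bowel surfaces after surgery. The arrays followed the small bowel of male mice, 56 days old per the labels, through the days in which such adhesions form. There were 2 arrays of bowel after laparotomy alone (sham) and 2 arrays each at 1, 3, 7 and 14 days after abrasion. Values are ratios to the mean of the sham arrays of the same feature, and the number of arrays limits their precision. Day minus sham differences of replicate pairs 1 and 2 correlated only weakly across features. The r was 0.16, 0.08, 0.10 and 0.18 at days 1, 3, 7 and 14. Genes named below were picked among features where both arrays agreed. The standard deviation of the log2 difference between replicates ranged from 0.48 at day 1 to 0.58 at day 3. The median standard error of a contrast was 0.26 (log2), and 0.19 with the replicate block.

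Day 1 against sham set the bowel 1 day after abrasion against sham RNA pooled from 4 times after laparotomy. Time since surgery was therefore not matched, here and at the later days, and cannot be told apart from abrasion. The lowest value among the genes named by the rule was that of Usp18. This gene, which removes the ubiquitin-like protein ISG15 and dampens interferon signalling, had a log2 difference of -1.38 ± 0.25, with ratios of 0.38 and 0.387 on the day 1 arrays and 0.935 and 1.065 on the sham arrays. Gbp2, an interferon-induced GTPase, was at -0.77 ± 0.19. Of the other interferon-inducible genes measured, Ifi27 was at -0.48 ± 0.35, and Tap1, at the floor on 6 of the 10 arrays, at -0.21 ± 0.18. Cubn, the ileal receptor for vitamin B12 bound to intrinsic factor, was at -1.07 ± 0.31, and the Polycomb gene Phc1 at -0.99 ± 0.27. Gmppb was at the floor on both day 1 arrays, at least 1.77-fold lower than sham. On the higher side stood Sort1 (0.84 ± 0.28), Scnn1b, a subunit of the epithelial sodium channel (0.72 ± 0.22), Sf3b3 (0.68 ± 0.21), Dpy19l3 (0.65 ± 0.16) and Lpcat3, an enzyme of phospholipid remodelling (0.63 ± 0.17). On the sham side 1 array was at the floor for Scnn1b and for Dpy19l3. Second features of Sort1 and Angel2 were nearer to 0, at 0.12 ± 0.14 and -0.01 ± 0.16.

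None of these passed limma's test: 0 of 5564 features did at day 1 (smallest adjusted p = 1), while 86 higher and 73 lower features had an unadjusted p under 0.05, which is 2.86% of those tested. In the fit with the replicate block, 350 features had such a p, 6.29% of those tested. All 5 measured genes of TGF-beta and BMP signalling lay above 0 (median 0.28), with Smad7 at 0.45 ± 0.28 and Ski at 0.39 ± 0.31, and all 7 endothelial markers did (median 0.19), with Emcn, at the floor on both sham arrays, at 0.38 ± 0.32. Flt4 was at the floor on 9 of the 10 arrays, and Smad4 had a sham mean of 0 (log2), as Emcn did. These signs therefore rest partly on bounds, and that of Smad4 may do so at the later days too. Camera passed 0 of 9 lists; its smallest adjusted p was 0.230, for TGF-beta and BMP signalling, and 0.491 with an estimated correlation, and 0 of their members passed the adjustment over the list alone.

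**Figure D1:**
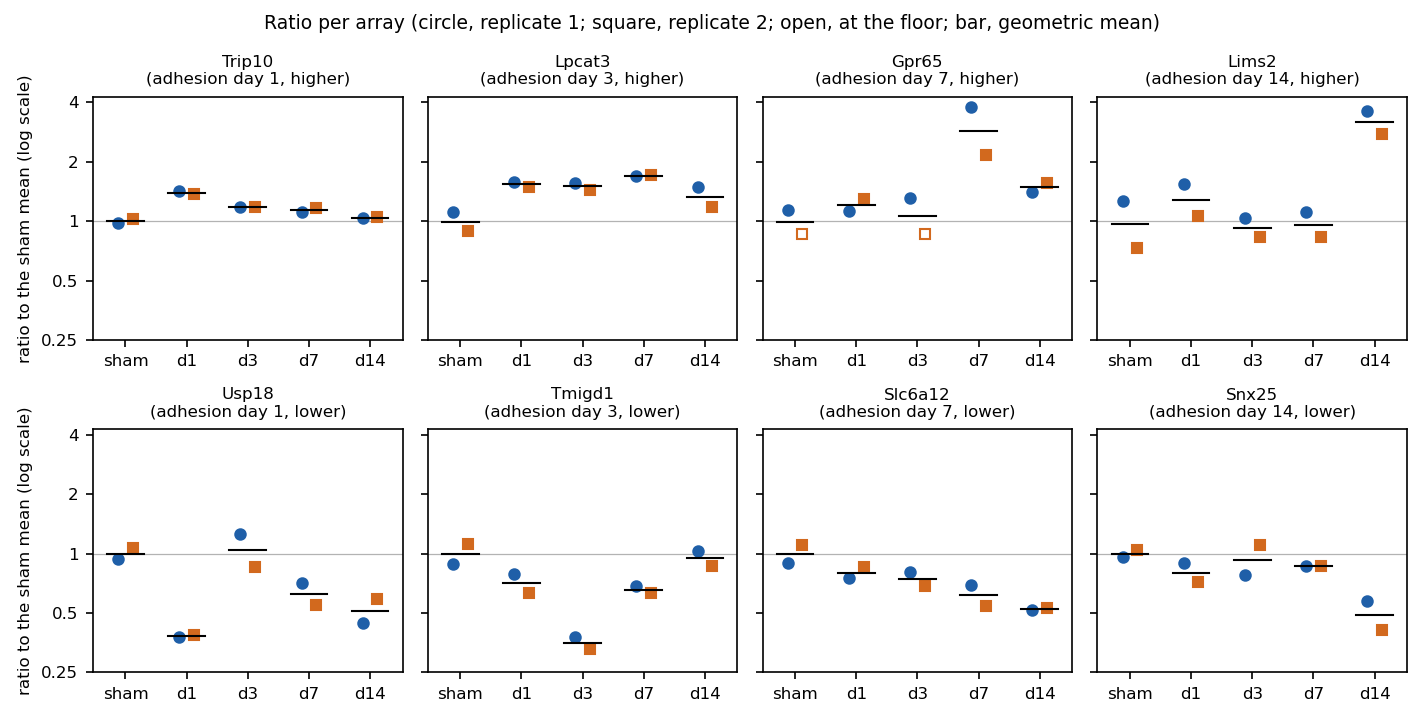
Ratio to the sham mean (vertical axis, log scale, no unit) on each of the 10 arrays for the first higher gene (top) and the first lower gene (bottom) of each day against sham that had not been drawn for an earlier day; groups are sham and days 1, 3, 7 and 14 (d1 to d14), circles are replicate 1, squares replicate 2, open symbols values at the floor, and bars geometric means. Usp18 stands at 0.38 and 0.387 at day 1, Tmigd1 at 0.376 and 0.33 at day 3, and Lims2 at 3.606 and 2.779 at day 14.

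Day 3 against sham showed its lowest value among the genes named by the rule in Tmigd1, an immunoglobulin-domain adhesion molecule of kidney and intestinal epithelium. It was at -1.50 ± 0.19, with ratios of 0.376 and 0.33 on the day 3 arrays against 0.883 and 1.117 in sham. Cdc25a, a phosphatase that drives cell cycle entry, was at -0.63 ± 0.17, and Mdm2, the ubiquitin ligase of p53, at -0.68 ± 0.21. Tnfaip8, a gene induced by tumour necrosis factor, was at -0.50 ± 0.15, but its second feature was at 0.00 ± 0.14. Papss2, which makes the sulphate donor for glycans and other substrates, was at 1.19 ± 0.36, Sort1 at 0.76 ± 0.28, the zinc transporter Slc30a7 at 0.73 ± 0.26, Lpcat3 at 0.60 ± 0.17 and Cpt1a, the gatekeeper of fatty acid entry into mitochondria, at 0.53 ± 0.19. Second features were lower for Sort1 (0.03 ± 0.14), Slc30a7 (0.29 ± 0.34) and Cpt1a (0.38 ± 0.37).

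In limma's test 0 of 5564 features passed at day 3 (smallest adjusted p = 0.594), and 112 had an unadjusted p under 0.05, 54 higher and 58 lower. Tmigd1 kept its sign under all alternatives, which its selection by full separation of the arrays largely fixed. It passed in the fit with position correction and replicate block (-1.25, adjusted p = 0.0272 by limma), added after the data were examined. In that fit 3 features passed. The others were 2 features without a gene name, 5383 at 1.97 and 420 at 1.28, singled out here after their values were seen. All 6 matrix proteases and inhibitors (median 0.17), all 5 TGF-beta and BMP genes (median 0.25) and all 5 fatty acid genes (median 0.13) lay above 0, while 4 of 5 cell cycle genes lay below. The median of the matrix proteases ranged from -0.10 to 0.48 with 1 array left out, so its direction rests on single arrays. In camera 0 of 9 lists passed; these first 3 lists shared the smallest adjusted p of 0.0958, and with an estimated correlation the smallest was 0.348. Cdc25a passed the adjustment over the list alone, the only member of the 9 tested lists to do so at any day; smaller lists were not adjusted on their own.

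Day 7 against sham had its highest value among the genes named by the rule in Gpr65, a proton-sensing receptor of lymphoid and myeloid cells, at 1.53 ± 0.32. Its ratios were 3.774 and 2.165 on the day 7 arrays, and 1 of the sham arrays was at the floor. Col14a1, a collagen that binds to fibrils, was at the floor on both sham arrays and at least 1.82-fold higher at day 7 (0.86 ± 0.19). Papss2 was at 1.34 ± 0.36, Ralgapa1 at 1.04 ± 0.34, Lpcat3 at 0.77 ± 0.17 and the peroxisome gene Pex11a at 0.67 ± 0.20. Lower values were found for Xab2 (-0.77 ± 0.21), the betaine transporter Slc6a12 (-0.69 ± 0.19) and Tmigd1 (-0.59 ± 0.19). H2-Ob, a gene of MHC class II antigen presentation (-0.58 ± 0.18), and Foxc2 (-0.55 ± 0.15) were lower too. Usp18 and Gbp2 were at -0.68 ± 0.25 and -0.46 ± 0.19. Other features of the same genes lay elsewhere: a second feature of Zfp318 was at -0.24 ± 0.24, against 0.83 ± 0.25 for the first, and 2 further features of Ralgapa1 were at 0.31 ± 0.49 and 0.05 ± 0.41.

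By limma 0 of 5564 features passed at day 7 (smallest adjusted p = 1), with 94 higher and 61 lower at an unadjusted p under 0.05. With position correction and replicate block 1 feature passed, the unnamed 5383 at 1.97. Among lists, fatty acid genes had a median of 0.36 (3 of 5 above 0, Cpt1a at 0.45 ± 0.19), epithelial junction genes 0.20 (Pkp2 0.53 ± 0.40, Tjp1 0.42 ± 0.38) and TGF-beta and BMP genes 0.17 (Fstl1 0.54 ± 0.24). Cldn2 and Cldn7 of the junction genes had a sham mean of 0 (log2), so the median of that list may rest partly on bounds. Flt1, a receptor of vascular growth factors, was at 0.49 ± 0.18, and the 7 endothelial markers together had a median of 0. Camera passed 0 of 9 lists (smallest adjusted p = 0.294, and 0.755 with an estimated correlation).

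Day 14 against sham held the largest number of small p-values among the days, and the highest value among the genes named by the rule was that of Lims2, which encodes PINCH-2, an adaptor of integrin-linked kinase at focal adhesions. Lims2 was at 1.72 ± 0.33, a 3.28-fold difference, with ratios of 3.606 and 2.779 against 1.267 and 0.733 in sham. Stxbp5, a regulator of vesicle fusion, was at 1.50 ± 0.29, Ttc36 at 1.06 ± 0.31, Pex11a at 0.96 ± 0.20, Lemd2 at 0.84 ± 0.24, the autophagy gene Atg5 at 0.83 ± 0.24 and Cpt1a at 0.66 ± 0.19. Bub1b and Zfp414 were at the floor on both sham arrays and at least 1.41-fold and 1.44-fold higher, but a second feature of Bub1b was at 0.17 ± 0.15, and at 0.01 after position correction. The second feature of Cpt1a was at 0.34 ± 0.37. Snx25 was at -1.04 ± 0.24, Usp18 at -0.96 ± 0.25, Slc6a12 at -0.92 ± 0.19, Xab2 at -0.86 ± 0.21, Pik3c2g at -0.79 ± 0.22 and Selenoi, an enzyme of phosphatidylethanolamine synthesis, at -0.68 ± 0.16.

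Limma passed 0 of 5564 features at day 14 (smallest adjusted p = 0.574), with 176 higher and 107 lower at an unadjusted p under 0.05, 5.09% of those tested. In the fit with the replicate block, which uses the pairing, 572 features had such a p, 10.3% of those tested. Under quantile normalization 168 features had such a p at day 14, against 150, 84 and 95 at days 1, 3 and 7. The lead of day 14 was smaller there. With position correction 2 features passed, Lims2 (1.90, adjusted p = 0.0194) and the unnamed 5383; with the replicate block as well, 6 passed, all higher, and the adjusted p of Lims2 by limma was 0.000846. Of the 6, Lims2 alone had a gene name. All 7 integrin and adhesion genes lay above 0 (median 0.19, Itga8, at the floor on 7 of the 10 arrays, 0.31 ± 0.17), all 5 crypt and Wnt genes did (median 0.14, Axin1 0.38 ± 0.14, its second feature -0.12), and so did 4 of 5 TGF-beta and BMP genes (median 0.31, Smad7 0.50 ± 0.28). Among 7 apoptosis genes 5 lay below 0 (median -0.02, and from -0.37 to 0.12 with 1 array left out). Camera passed 0 of 9 lists (smallest adjusted p = 0.200, and 0.531 with an estimated correlation).

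Differences by feature number covered whole areas of the array at each day, with autocorrelations of 0.24, 0.34, 0.29 and 0.36 at a distance of 32 features for days 1, 3, 7 and 14. Values of single genes contain this trend. When the position surface was subtracted, the day 14 values of Xab2 moved from -0.86 to -0.52, Slc6a12 from -0.92 to -0.59 and Axin1 from 0.38 to 0.09. Smad7 moved from 0.50 to 0.26, Stxbp5 from 1.50 to 1.11 and Pex11a from 0.96 to 0.72. Other values grew, such as Lims2 from 1.72 to 1.90 and the second feature of Cpt1a from 0.34 to 0.48. The day 7 values of Xab2 moved from -0.77 to -0.50, Slc6a12 from -0.69 to -0.44, Tmigd1 from -0.59 to -0.37, Foxc2 from -0.55 to -0.36 and Gbp2 from -0.46 to -0.30. On the higher side, Flt1 moved from 0.49 to 0.31, Fstl1 from 0.54 to 0.36 and Tjp1 from 0.42 to 0.28, and the day 1 value of Emcn from 0.38 to 0.20. The medians of the endothelial markers at day 1 (0.19 to 0.11), the TGF-beta and BMP genes at day 3 (0.25 to 0.12) and the integrin and adhesion genes at day 14 (0.19 to 0.11) moved towards 0 as well. With position correction and replicate block, the day 3 medians of matrix proteases (0.17 to 0.22) and fatty acid genes (0.13 to 0.18) moved away from 0.

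**Figure D2:**
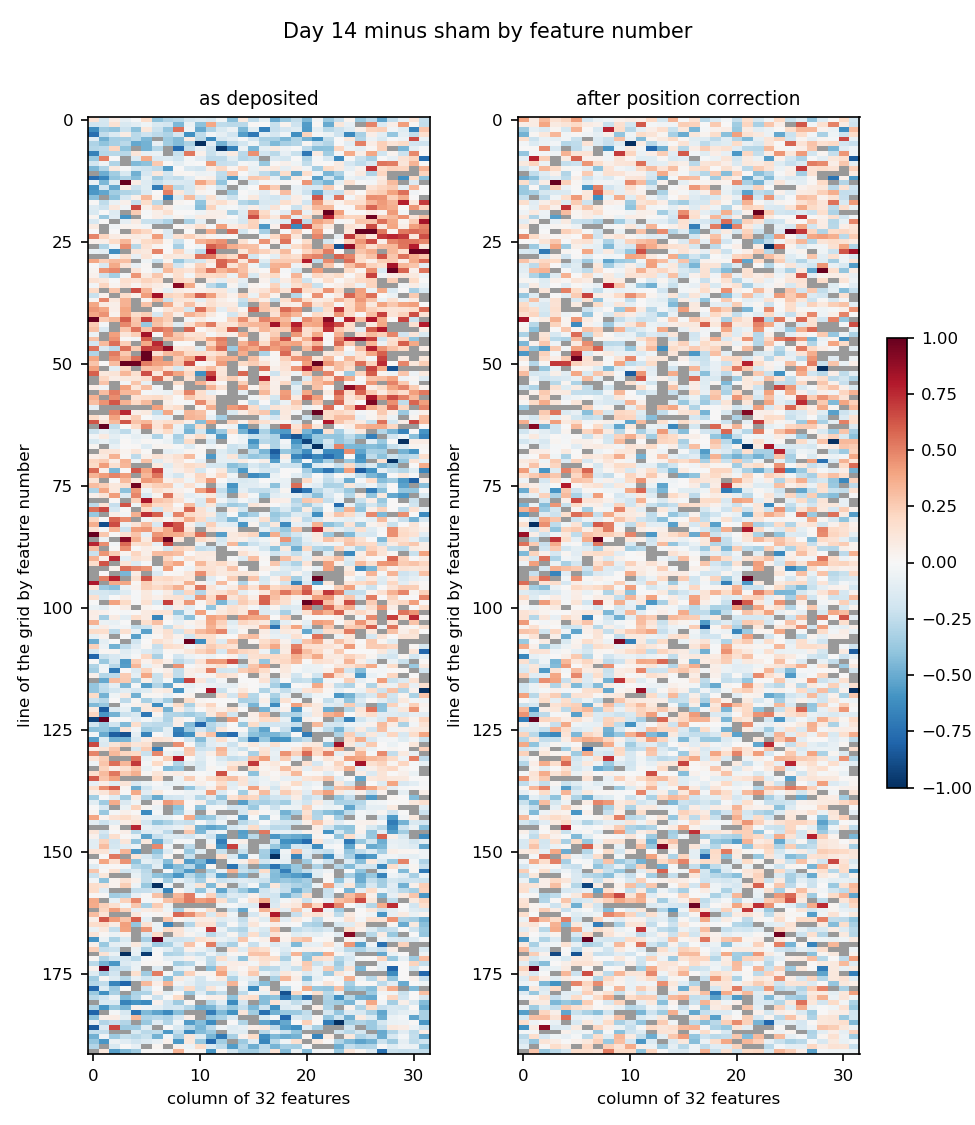
Log2 difference of day 14 minus sham (colour, from -1 in blue to 1 in red; grey, not tested) for each feature placed by its number in a grid of 32 columns (horizontal axis) and lines counted from 0 (vertical axis), as deposited (left) and after position correction (right). Areas of one sign on the left, with an autocorrelation of 0.36 at a distance of 32 features, are weaker on the right.

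Differences between successive days followed the time course itself, with the spread still taken over all 10 arrays. From day 1 to day 3, Usp18 differed by 1.44 ± 0.25 and Gbp2 by 1.02 ± 0.19, to log2 values of 0.06 and 0.25 against sham, while Tmigd1 had ratios of 0.376 and 0.33 at day 3 against 0.791 and 0.63 at day 1. From day 3 to day 7, Gpr65, with 1 day 3 array at the floor, differed by 1.43 ± 0.32, Tmigd1 by 0.90 ± 0.19 and Col14a1 by 0.76 ± 0.19, while Gbp2 was lower again (-0.71 ± 0.19). From day 7 to day 14, Lims2 differed by 1.73 ± 0.33 and Papss2 by -1.44 ± 0.36, and Pou2af1, a coactivator of B cells, by -0.90 ± 0.19. By limma 0 features passed in each of the 3 comparisons, with 120, 95 and 167 features at an unadjusted p under 0.05. With position correction and replicate block, Lims2 (1.66, adjusted p = 0.00250 by limma) passed between days 7 and 14, together with 1 lower feature annotated to several genes.

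Across the 5 groups, the genes with the smallest p in limma's F test were Tmigd1, Usp18, Gmppb, Lims2, Gm27008, Gbp2, Pik3c2g, Selenoi, Stxbp5 and Papss2. Of these, Tmigd1 was lowest at day 3 (-1.50) and at -0.07 by day 14, Papss2 stood high at days 3 and 7 (1.19 and 1.34) and at -0.10 at day 14, and Stxbp5 went from 0.23 through 0.38 and 0.69 to 1.50. Of 5564 features 0 passed the F test (smallest adjusted p = 1), and 150 had an unadjusted p under 0.05; with position correction and replicate block 5 passed, among them Lims2 (adjusted p = 0.00383) and Tmigd1 (adjusted p = 0.0386).

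In several lists the centre near 0 depended on how it was taken. Median and mean had different signs for cell cycle genes at day 1 (0.01 and -0.06), junction genes at day 3 (-0.01 and 0.01) and day 14 (0.03 and -0.01), crypt genes at day 3 (-0.02 and 0.05), integrins at day 7 (-0.0005 and 0.01) and fatty acid genes at day 14 (-0.04 and 0.03). None of these lists passed camera, which sets a list against all other genes. Its direction was down for cell cycle genes at day 1 (adjusted p = 0.691), integrins at day 7 (0.785) and junction genes at day 14 (0.864), and up for the other 3. For fatty acid genes at day 1 its direction was up (adjusted p = 0.955), with a median of -0.07 and a mean of -0.01.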

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

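The tests of differences between days and the regrouping of arrays in this part were chosen after the values were seen. For 7 genes named in the report, all arrays of 1 day lay above both sham arrays and all arrays of another day below both, at days that the report does not set against each other. The differences below are the later minus the earlier day on the log2 scale. Gmppb, an enzyme of GDP-mannose synthesis, differed by 1.43 between days 1 and 14, from -0.83 ± 0.22 to 0.60 ± 0.22, with both day 1 arrays at the floor. Cubn differed by 1.30 between days 1 and 7, from -1.07 ± 0.31 to 0.23 ± 0.31. Pik3c2g, a lipid kinase, differed by -1.25 between days 1 and 14, from 0.46 ± 0.22 to -0.79 ± 0.22. Gm27008 differed by 1.05 between days 3 and 14. Slc35b2, a transporter of the sulphate donor into the Golgi, differed by -0.77 between days 1 and 14, Selenoi by -0.76 between the same days, and Gbp2 by -0.68 between days 3 and 14. In limma's test of these day pairs 0 of 5564 features passed for days 7 and 1, 14 and 1, or 14 and 3, with 158, 170 and 201 features at an unadjusted p under 0.05. With the replicate block the counts past the threshold were 0, 0 and 1, the last being Lims2 (1.77, adjusted p = 0.0473), and 356, 388 and 453 had an unadjusted p under 0.05. Over all features, 76, 61 and 61 parted in this way for these day pairs, fewer than the 124 of a random order of 6 independent arrays, which ignores ties at the floor and the pairing by replicate number. When arrays of different groups were joined instead, 1 of each replicate number so that the pairing was kept, the medians of 6 regroupings were 45, 44 and 64 and the highest counts 81, 73 and 84. Of the 6, 1, 1 and 3 were as large as the real count, too few regroupings to tell the real counts from chance.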

How the results depend on the processing

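The position correction, alone and with the replicate block, and the limit on features at the floor were chosen after the data were examined. The log2 differences of all 110 named values kept their sign in 2304 of 2304 recomputed values, and 4 of these passed the threshold: Lims2 at day 14 under position correction, and, with the replicate block added, Lims2 at day 14 and from day 7 to 14, and Tmigd1 at day 3. The kept signs were largely fixed in advance. Named genes had both arrays of 1 group beyond both of the other, so leaving out 1 array could not reverse them. The replicate block, the variance trend and the threshold leave a difference as it is. The count of features past the threshold was 0 for each of the 7 contrasts and the F test in limma. It stayed 0 under quantile normalization, median centring, the pseudocount, the variance trend, array weights, the threshold of 0.1 and the limit on features at the floor. With the groups compared alone, run for the contrasts and not for the F test, it stayed 0 too. With the replicate block, which uses the pairing by number, it was also 0 for each contrast and the F test (at a threshold of 0.1, 2 at day 14 and 1 between days 7 and 14), at 350, 270, 328 and 572 features with an unadjusted p under 0.05 for days 1, 3, 7 and 14 (159, 112, 155 and 283 without the block) and 403 for the F test, so the block changed no call; the smallest adjusted p was 0.0562 between days 7 and 14, and 0.0585 at day 14 against sham. Under position correction the count moved to 2 at day 14. Under position correction and replicate block it moved to 3 at day 3, 1 at day 7, 6 at day 14, 2 between days 7 and 14, and 5 in the F test; the cause was not tested. With 1 array left out, the counts ranged from 0 to 1 at day 1, 0 to 1 at day 3, 0 to 3 at day 7, 0 to 0 at day 14, 0 to 1 between days 1 and 3, 0 to 3 between days 3 and 7, 0 to 3 between days 7 and 14, and 0 to 2 in the F test. The calls of the contrasts came without day 1 replicate 2, day 3 replicate 1 or day 7 replicate 2, from features at the floor on the 9 other arrays, where the array that is left alone in its group is assumed to vary like the other groups. The count of lists past the threshold was 0 at each day and ranged from 0 to 1 at day 3 with 1 array left out (without day 3 replicate 2, matrix proteases, median 0.48) and from 0 to 0 at the other days. It was 2 at day 3 under position correction and replicate block: matrix proteases (0.22) and fatty acid genes (0.18), both with an adjusted p of 0.0376, and the cause was not tested. In the fit of all arrays without correction or block, no list passed with an estimated correlation or with the mean of all features. Neither was combined with the settings in which lists passed. List medians took the other sign in 42 of 648 recomputed values, none past the threshold (smallest adjusted p 0.370). Among them were lists with reported medians away from 0: matrix proteases at days 3 (0.17) and 7 (0.22) and apoptosis genes at day 3 (-0.17). Under quantile normalization these were junction genes at day 3 (0.0027) and integrins at day 7 (0.0053); under median centring, integrins (0.0096) and cell cycle genes (0.00054) at day 7; under the mean of all features, cell cycle genes at day 1 (-0.0214). Under position correction, with or without the replicate block, they were cell cycle genes at days 1 (-0.0208) and 14 (-0.0241), fatty acid genes at days 1 (0.0247) and 14 (0.00904), crypt genes at day 3 (0.105) and apoptosis genes at day 7 (-0.0548). With 1 array left out, medians ranged at day 1 from -0.136 to 0.0134 (cell cycle), -0.0821 to 0.199 (fatty acid) and -0.0167 to 0.180 (crypt). At day 3 they ranged from -0.0615 to 0.0501 (junctions), -0.0249 to 0.153 (crypt), -0.389 to 0.0534 (apoptosis), -0.469 to 0.0213 (cell cycle) and -0.102 to 0.478 (matrix proteases). At day 7 they ranged from -0.161 to 0.0246 (cell cycle), -0.0815 to 0.228 (apoptosis), -0.119 to 0.314 (matrix proteases), -0.225 to 0.0502 (integrins) and -0.0457 to 0.175 (crypt). At day 14 they ranged from -0.369 to 0.124 (apoptosis), -0.0349 to 0.0502 (junctions), -0.0163 to 0.221 (cell cycle) and -0.134 to 0.131 (fatty acid). The causes of these changes were not tested. The planned filter on dim features was not run, since a ratio does not show brightness and the filter would select on the outcome, and signal over background is therefore unknown here.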

Other observations

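The tests of position, of Lims2 and of the replicate numbers, and the comparison of the mean of the 4 days with sham and its regroupings, were chosen after the values were seen; the test of features that share a gene was written before its result. Over the mean of the 4 days, Lpcat3 lay 1.52-fold above sham (0.60 ± 0.14) and above both sham arrays on all 8 day arrays. Ttc36 (0.83 ± 0.24) and Txnrd1, a reductase of the thioredoxin system (0.73 ± 0.28), did so too, while Slc6a12 (-0.59 ± 0.15), Xab2 (-0.62 ± 0.17) and H2-Ob (-0.47 ± 0.14) lay below both on all 8. With position correction and replicate block Slc6a12 was at -0.31 and Xab2 at -0.33. Such features numbered 108 above and 71 below, of 5564, both fewer than the 124 of a random order of 10 independent arrays, which ignores ties at the floor and the pairing by replicate number. When the 2 sham arrays were replaced by arrays of 2 different groups, 1 of each replicate number, the 20 regroupings gave from 23 to 88 above (median 43.5) and from 23 to 139 below (median 60). None of them reached 108 above, and 8 reached 71 below, so whether 108 is an excess depends on the reference. The regroupings split groups that the real count kept whole, so likeness within a group may lower their counts. For the mean of the 4 days limma passed 0 of 5564 features, with 193 at an unadjusted p under 0.05, and 0 with the replicate block, with 394. It passed 1 with position correction alone, with 158 at an unadjusted p under 0.05 (smallest adjusted p 0.0397). With position correction and replicate block 2 features without a gene name passed, 5383 at 1.78 ± 0.16 and 420 at 1.18 ± 0.12, both with an adjusted p of 0.0122 and both singled out after their values were seen.

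Among genes of lists too small to test, the ileal hormone Fgf15, which restrains bile acid synthesis, was at -0.83 ± 0.28 at day 1 and -0.06 ± 0.28 at day 14. Its feature is next to that of Gbp2 on the array. Col11a1 was at 0.36, 0.63, 0.60 and 1.00 over days 1, 3, 7 and 14, each ± 0.34. Loxl1 of the same list went the other way, at -0.27, -0.23, -0.27 and -0.27, each ± 0.18. The mean of Loxl1 was the same -0.29 (log2) at days 1, 7 and 14, as a floor would give. Its differences at these days may therefore be bounds, and their direction rests on the sham arrays. Markers of other tissues lay within 2 standard errors of 0 at each day: the hepatocyte gene Tat at -0.16, -0.21, -0.18 and 0.67 (± 0.48), and the skeletal muscle gene Casq1 at 0.08, 0.15, 0.02 and -0.23 (± 0.28). These relative values do not show how much of such tissue the samples held.

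Features of the same gene were set against each other across 199 genes with 2 or more tested features. If both measured the same transcript, their day 14 differences should correlate above random re-pairings. The correlation across genes was 0.104 at day 14, against a 95th percentile of 0.118 for 10000 re-pairings (permutation p = 0.0743, one-sided, adjusted over 8 comparisons 0.0849), too close to decide. The margin by which this is read as undecided was set after the value was seen. At days 1, 3 and 7 it was 0.201, 0.185 and 0.172 (permutation p = 0.00190, 0.00370 and 0.00810, adjusted 0.00740, 0.00740 and 0.0130). After position correction it was 0.186, 0.214, 0.110 and 0.0510 at days 1, 3, 7 and 14 (permutation p adjusted 0.00740, 0.00740, 0.0780 and 0.243), so the call at day 7 was lost. Sharing a name may account for a small part of the variation at days 1 and 3; genes are not independent replicates.

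Features close in number deviated together even between the sham arrays. In the sham replicate difference of the 3072 features of lower number, the autocorrelation at distances of 8 to 60 features was highest at 32. The period had been seen before over all features, so this split tests its repetition and not its discovery. In the features of higher number it was 0.230 at 32 features, against a median of 0.112 at 12 to 20 features (standard error 0.0199). This rise is what lines of a membrane would give, and it argues against an order of clones with a steady fall-off. An order of clones that repeats with the same period was not tested. Uneven hybridisation or staining is a candidate explanation, and no biological explanation was tested.

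Lims2 at day 14 passed under position correction, as did the unnamed 5383. The 18 tested features within 2 lines and 2 columns of it had a median of -0.211 at day 14, which argues against a local bright area. The standard error of that median, 0.05, was taken across these features as if they were independent. Neighbours deviate together, so it may be too small. The replicate pairs differed by 1.51 and 1.92, but Lims2 was picked by a rule that asks for both day arrays above both sham arrays, so an effect of one replicate set stays open. Lims2 has 1 feature, so the identity of the clone and cross-hybridisation stay open too. A biological difference in this focal adhesion gene was not tested apart from these and is open as well: the adjusted p of Lims2 by limma was 0.000846 with position correction and replicate block, 0.0585 with the replicate block alone, 0.593 with neither, and 0.999 under quantile normalization, where the log2 difference was 1.53 against 1.72.

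Arrays of the same replicate number deviated together, with a median correlation of 0.622 between groups across features. A shared trend of the smooth position surface alone is argued against, since the lowest correlation was still 0.458 after that surface was subtracted. Position effects finer than the surface were not tested. The cohorts of mice named in the design and separate runs of labelling or hybridisation cannot be told apart, as no label separates them, and either could give these values.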
